A study of Cavia porcellus with 28 samples.

How the data were processed

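Gene expression was measured by sequencing of polyadenylated RNA from the cortex of guinea pigs of 2 strains, Hartley (Dunkin Hartley, an outbred albino laboratory strain) and Pigmented, at 5 and 15 months of age and in both sexes. Per the labels' protocols, RNA was extracted with Trizol and spin columns and libraries were made with an Illumina TruSeq polyA kit. Each of the 28 libraries has a different animal label, so the libraries are taken as biological replicates, and no animal was measured at both ages. The labels of Hartley 5 months female replicate 2 and Pigmented 5 months male replicate 3 share a number and differ by a letter. Hartley had 3 animals and Pigmented 4 animals in each combination of age and sex, which gives 8 groups.

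The deposited table holds whole-number read counts per gene for the 28 libraries, with no normalisation. The submitters' processing notes list STAR and DESeq2, with no version, and the form of the table is that of STAR gene counts. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart, and counts of near-identical gene copies are uncertain. Columns were matched to animals by the animal number in the labels, with its letter where there is one. For 1 animal the match rests on that number alone, because the rest of its column name differed from its label. No column was left without a sample.

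The table gives 26855 gene IDs without names, and the gene reference at hand (assembly mCavPor4.1) lists no Ensembl IDs, so 0 IDs were matched to a symbol. The files do not pair IDs with names. The 50 lists of pathway and cell type genes fixed before the data were examined could therefore not be tested, and neither could the planned rule for naming genes by symbol. In its place, set after the table was seen to hold no symbols, the text names for each comparison at most the 2 IDs with the smallest p in each direction among those with a mean of at least 1 CPM (counts scaled to the library total times its TMM factor). In comparisons with no gene past the threshold these IDs are given as values only.

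Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr over the 8 groups (minimum count 10, minimum total count 15), which left 16026 tested genes holding 99.96% of all counts, and 10829 IDs were removed. Libraries were scaled with TMM factors. A model with 1 mean for each of the 8 groups was fitted over all 28 libraries, and contrasts were tested with edgeR's robust quasi-likelihood F-test. Age was tested within each strain (15 minus 5 months), strain within each age (Hartley minus Pigmented), both as means over the sexes, and sex over the 4 combinations of strain and age. The differences of the age effect between strains and between sexes were tested as interactions. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and standard errors (SE) are the log2 fold change divided by the square root of F. Age averaged over both strains and strain averaged over both ages were added after the separate counts had been seen. CPM values are given as mean ± SD over animals, and log2 CPM for distances and principal components used a prior count of 2.

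Total counts ranged from 17150437 to 41906016 per library. On simulated counts with the real depths and spreads over 16026 genes, the test recovered 41.8% of 1.5-fold, 71.6% of 2-fold and 86.4% of 4-fold changes for age in Hartley, with 15 false among 148 calls. It recovered 53.7%, 73.1% and 95.5% of these for age in Pigmented (9 false of 157), 53.7%, 76.1% and 92.4% for strain at 5 months (6 false of 154), and 55.2%, 73.1% and 93.9% for strain at 15 months (3 false of 151). For sex it recovered 71.6%, 83.6% and 98.5% (6 false of 175). The simulation drew each gene independently from 1 mean and its fitted spread. It held no deviating library and no correlation between genes, so these rates are not the power or error rate on the real libraries. Counts are read counts without molecular identifiers, so intervals on counts cover counting error only. No pair of the 36 replicate pairs was close enough to be 1 library counted again: the chi-square per degree of freedom ranged from 7.10 to 133.

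Alternatives fixed before the data were examined were DESeq2's size factors (RLE), DESeq2 1.42.0 as the test, limma 3.58.1 with voom and with voom sample weights, no filter, a filter at a mean of 1 CPM, only the libraries compared, sex as an additive covariate, the sample-sheet number from the labels as a covariate, and leaving out each library in turn. Surrogate variables (sva 3.50.0, 4 variables as estimated from the data, and 1, 2 or 3) were added after the data were seen. The labels give no sequencing batch or date. To see what chance gives, labels of 1 factor were shuffled among libraries that share the other 2 factors, and 100 splits, the real one included, were fitted in the same way. Sample weights were fitted on these splits for age within each strain only.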

Results

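The study set guinea pigs of strains that carry no transgene beside each other to look for features of human brain ageing, and its design crosses strain, age and sex. The cortex transcriptome was counted in 28 animals: 6 Hartley at 5 months, 6 Hartley at 15 months, 8 Pigmented at 5 months and 8 Pigmented at 15 months, with as many females as males in each. Library totals had a median of 19315111 counts and ranged from 17150437 to 41906016. The deepest libraries were Pigmented 5 months male replicate 1 at 41906016 counts and Pigmented 15 months female replicate 4 at 37649824, and the next held 27712516. Between 16865 and 19168 IDs had at least 1 count per library, and the 10 most abundant IDs took 3.04% to 4.34% of the counts.

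Strain took more of the variation between animals than age or sex did. Over all tested genes it held 7.31% of the variance of log2 CPM, more than shuffled strain labels gave (permutation p = 0.009, Benjamini-Hochberg adjusted p = 0.027 over 3 factors, 28 animals). Age took 5.17% (permutation p = 0.0975, adjusted p = 0.1133) and sex 4.64% (permutation p = 0.1133, adjusted p = 0.1133), neither beyond shuffled labels. Principal component 1 held 21.5% of the variance and set Hartley 5 months male replicate 2, at 97.7, apart from the other 27 libraries, which lay at 37.9 or below. Component 3, with 9.78% of the variance, had a mean of 10.1 in Hartley and -7.60 in Pigmented (permutation p = 0.0049, adjusted p = 0.0441 over 9 tests of 3 components and 3 factors).

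**Figure D1:**
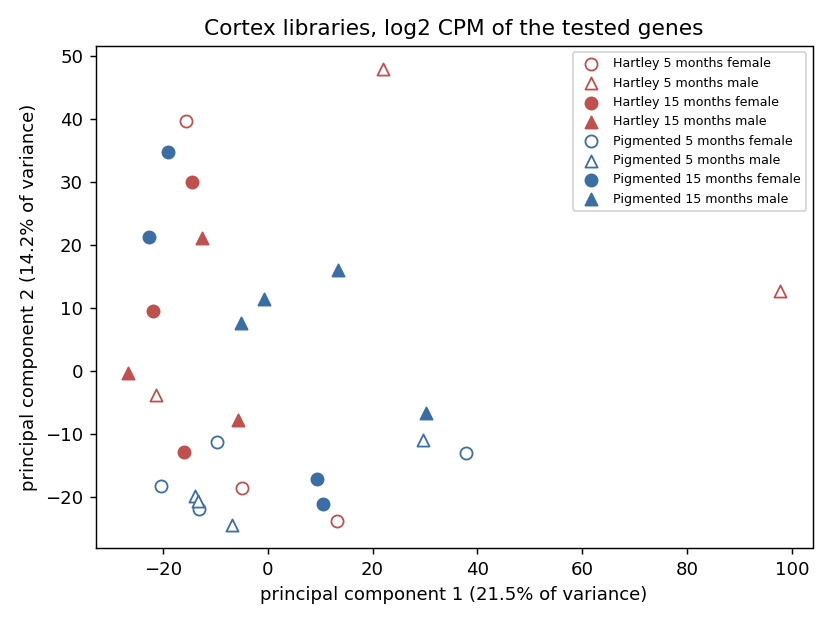
Each point is 1 cortex library placed by principal components 1 and 2 of log2 CPM (no unit), with colour for strain, filled symbols for 15 months, open symbols for 5 months and shape for sex. Hartley 5 months male replicate 2 lies at 97.7 on component 1, while the groups overlap elsewhere.

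The Hartley and Pigmented cortex differed at 5 months in 70 genes, 43 higher and 27 lower in Hartley (edgeR quasi-likelihood test, adjusted p under 0.05), of which 35 differed by more than 2-fold. ENSCPOG00000021466.2 was far lower in Hartley, at 1.27 ± 0.367 CPM (SD, n = 6) against 21.2 ± 8.06 CPM (SD, n = 8), a log2 fold change of -4.03 (SE 0.358, adjusted p = 5.4e-07). ENSCPOG00000008804.4 was at 21.3 ± 3.68 CPM in Hartley and 49.8 ± 5.88 CPM in Pigmented, a log2 fold change of -1.22 (SE 0.112, adjusted p = 5.4e-07). Among the genes higher in Hartley, ENSCPOG00000039622.1 was at 5.51 ± 3.85 against 0.884 ± 0.245 CPM (log2 fold change 2.36, SE 0.289, adjusted p = 7.1e-05). ENSCPOG00000007596.4 was at 8.17 ± 0.497 against 4.75 ± 0.576 CPM (log2 fold change 0.78, SE 0.10, adjusted p = 0.000137). Without Hartley 5 months male replicate 1 the count rose to 1937 genes, and the balance turned to 597 higher and 1340 lower in Hartley (30.8% higher against 61.4%). That fit keeps male replicate 2 of the same group, which lay at 97.7 on component 1. Without replicate 2 instead, the count stayed within 1.5 times of 70. The count rose to 108 without Pigmented 5 months female replicate 1 and fell to 45 without Hartley 5 months female replicate 3. With the sample-sheet number as a covariate it was 39, of which 37 were among the 70. DESeq2 called 325 genes, 231 higher and 94 lower, and limma-voom with sample weights 5296, with the balance turned to 2340 higher and 2956 lower (44.2% higher). Sample weights called up to 4728 genes in Hartley under shuffled age labels, and they were not fitted on shuffled strain labels.

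At 15 months 62 genes differed between the strains, 33 higher and 29 lower in Hartley, and 32 of them by more than 2-fold. The IDs lower in Hartley with the smallest p were those of the 5-month comparison. ENSCPOG00000021466.2 stood at 1.31 ± 0.659 CPM (SD, n = 6) in Hartley and 26.95 ± 14.6 CPM (SD, n = 8) in Pigmented, a log2 fold change of -4.33 (SE 0.356, adjusted p = 1.3e-07 by edgeR). ENSCPOG00000008804.4 stood at 22.4 ± 1.70 and 55.6 ± 11.2 CPM, a log2 fold change of -1.31 (SE 0.112, adjusted p = 1.3e-07). ENSCPOG00000003744.4 was higher in Hartley at 7.71 ± 3.44 against 0.508 ± 0.284 CPM (log2 fold change 3.90, SE 0.420, adjusted p = 7.6e-06). ENSCPOG00000031846.1 was higher in Hartley at 48.9 ± 8.63 against 14.5 ± 2.76 CPM (log2 fold change 1.75, SE 0.207, adjusted p = 2.7e-05). The count was 38 without Pigmented 15 months male replicate 1, 40 without Hartley 15 months male replicate 2, and 106 without Hartley 5 months male replicate 2, a library of the other age. With only the 14 libraries of that age in the fit, 161 genes passed, 93 higher and 68 lower. DESeq2 called 166 genes, 82 higher and 84 lower, and limma-voom with sample weights 639, 359 higher and 280 lower.

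Most genes called for strain at 1 age went the same way at the other, but the tested genes as a whole did not. Of the genes called at each age, 16 were higher in Hartley at both, where independent lists would share 0.0885, and 14 were lower at both, where independent lists would share 0.0489. No gene was called in opposite directions. All 62 genes called at 15 months had the same sign at 5 months, and 64 of the 70 called at 5 months had the same sign at 15 months. Over all 16026 tested genes 46.7% had the same sign at both ages (Pearson 0.313, Spearman -0.0359), and among the 10219 with a mean of at least 10 CPM the correlations were 0.0809 and -0.119. No library enters both comparisons, but both come from 1 fit with a shared spread per gene, so the lists are not fully independent. Averaged over both ages, a comparison added after these counts were seen, 257 genes differed, 154 higher and 103 lower in Hartley, and 63 of them by more than 2-fold, with a median absolute log2 fold change of 0.54. In 8 of all 16026 tested genes the CPM ranges of the 12 Hartley and 16 Pigmented animals did not overlap, where chance would give 0.00105, and 7 of these were among the 257. That averaged count was 409 without Hartley 5 months male replicate 1, 558 without Hartley 5 months male replicate 2, and 154 with the sample-sheet number as a covariate, 134 of them among the 257. DESeq2 called 560 genes over both ages, 335 higher and 225 lower, and limma-voom with sample weights 2319, 1192 higher and 1127 lower. With 4 surrogate variables 462 genes were called, 239 higher and 223 lower. With 3 of them the balance turned, with 811 genes called, 377 higher and 434 lower.

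**Figure D2:**
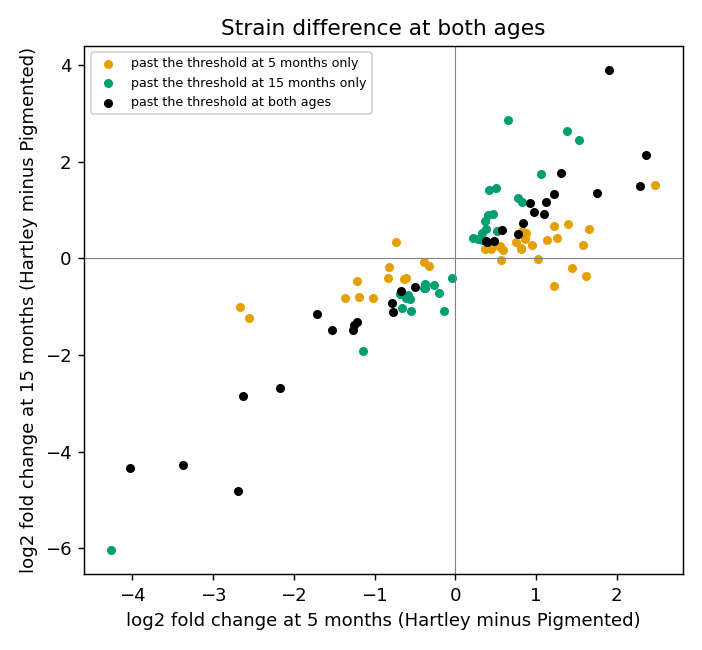
Each point is 1 gene past the threshold in at least 1 age, with the log2 fold change Hartley minus Pigmented at 5 months on the x axis and at 15 months on the y axis, coloured by the age at which it passed. The 30 genes past the threshold at both ages, 16 higher and 14 lower in Hartley, all lie in the quadrants of equal sign.

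**Figure D3:**
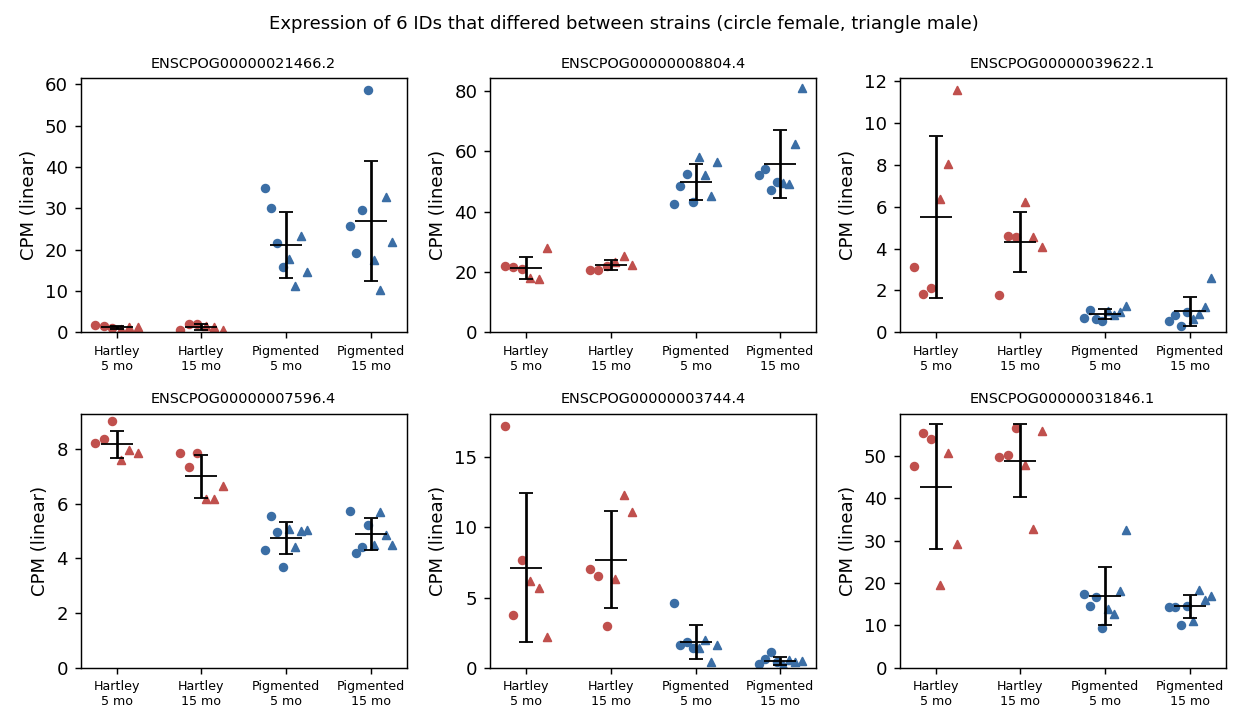
Points are CPM values (linear axis) of single animals for the 6 IDs named for strain, by strain and age, with the mean and SD as bars. ENSCPOG00000021466.2 stays at or below 2.07 CPM in the 12 Hartley animals and at or above 10.3 CPM in the 16 Pigmented animals.

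Between 5 and 15 months no gene passed the threshold in either strain. In Hartley 2323 genes had an unadjusted p under 0.05, where 801.3 would be expected by chance, 1173 of them higher and 1150 lower at 15 months, and the smallest adjusted p was 0.0913 (edgeR). DESeq2 called 35 genes, 27 higher and 8 lower, limma-voom 0, and limma-voom with sample weights 2350, 1558 higher and 792 lower. The number with an unadjusted p under 0.05 was 1370 with only the Hartley libraries in the fit and 903 with 4 surrogate variables. It was 2643 with the sample-sheet number as a covariate, 2813 in limma-voom and 5151 in limma-voom with sample weights. The lowest p of each direction belonged to ENSCPOG00000031413.1, at 0.680 ± 0.200 CPM (SD, n = 6) at 5 months and 2.98 ± 2.45 CPM (SD, n = 6) at 15 months (log2 fold change 2.13, SE 0.385), and to ENSCPOG00000025982.2, at 10.2 ± 3.26 and 3.87 ± 0.579 CPM (log2 fold change -1.40, SE 0.266). The log2 fold change of ENSCPOG00000031413.1 was 1.36 without Hartley 15 months female replicate 2, which stood at 7.63 CPM. It ranged from 0.98 to 2.35 over the alternatives, and that of ENSCPOG00000025982.2 from -1.58 to -1.17. Both had an adjusted p of 0.0913 in edgeR, and over the alternatives it ranged from 0.000496 to 0.848 for the former and from 0.000642 to 0.479 for the latter. The result depends on single libraries: without Hartley 5 months male replicate 1, 2408 genes passed, 1696 higher and 712 lower, and 5528 had an unadjusted p under 0.05, while this number fell to 1003 without Hartley 5 months male replicate 2, to 1300 without Hartley 15 months male replicate 2 and to 1526 without Hartley 5 months female replicate 3.

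In Pigmented 1269 genes had an unadjusted p under 0.05 against 801.3 by chance, 716 higher and 553 lower at 15 months, and the smallest adjusted p was 0.287 (edgeR). Without Pigmented 15 months female replicate 1 the number with an unadjusted p under 0.05 was 826. DESeq2 called 21 genes, 18 higher and 3 lower, and limma-voom 0. The balance turned in limma-voom with sample weights, which called 700 genes, 279 higher and 421 lower, and in edgeR with only the Pigmented libraries in the fit, which called 5 genes, 1 higher and 4 lower. ENSCPOG00000023432.2 stood at 8.28 ± 1.14 CPM (SD, n = 8) at 5 months and 12.9 ± 1.35 CPM (SD, n = 8) at 15 months (log2 fold change 0.64, SE 0.126, 0.44 to 0.71 over the alternatives, adjusted p = 0.287 in edgeR, 0.00229 to 0.745 over the alternatives). ENSCPOG00000003744.4, which was higher in Hartley at both ages, stood at 1.86 ± 1.21 and 0.508 ± 0.284 CPM (log2 fold change -1.85, SE 0.413, -2.07 to -1.38 over the alternatives, adjusted p = 0.382 in edgeR, 0.00292 to 0.877 over the alternatives). Over both strains together 0 genes passed in edgeR, 1917 had an unadjusted p under 0.05 (3439 without Hartley 5 months male replicate 1), and DESeq2 called 60. The fitted change with age was under 1.5-fold for 93.3% of the tested genes in Hartley and for 95.7% in Pigmented. For strain this share was 93.4% at 5 months and 94.3% at 15 months, so it does not set age apart.

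**Figure D4:**
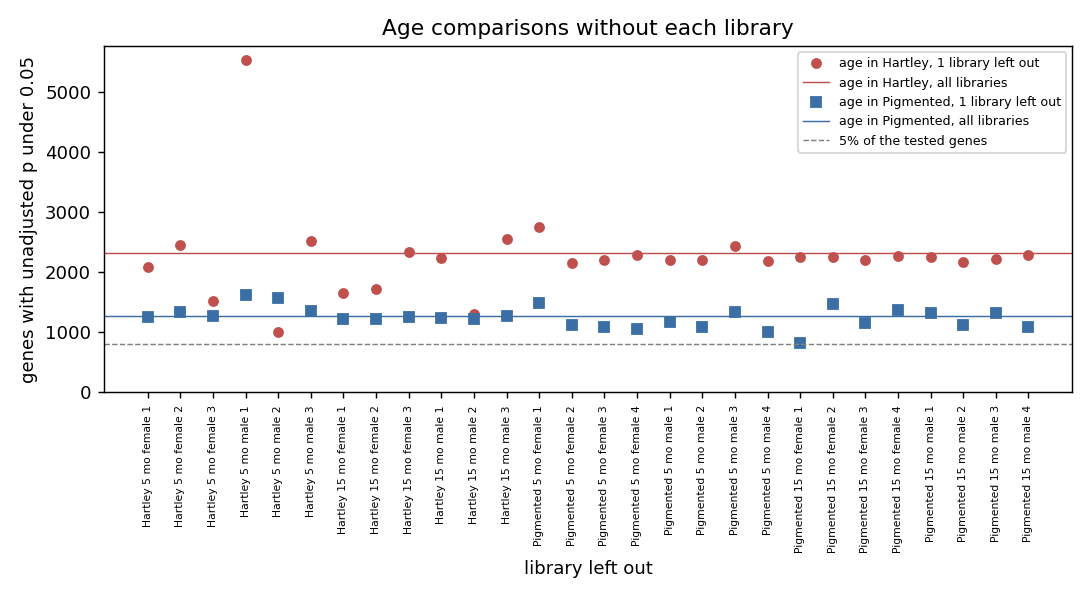
Points give the number of genes with an unadjusted p under 0.05 for age (linear y axis) after leaving out the library on the x axis, in Hartley and in Pigmented, with lines at the counts with all libraries and at 5% of the tested genes. Without Hartley 5 months male replicate 1 the Hartley count is 5528 and without male replicate 2 it is 1003.

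The age differences of the strains were not shown to differ from each other. The interaction of age and strain had 0 genes past the threshold in edgeR, 1698 with an unadjusted p under 0.05, and a smallest adjusted p of 0.224, while DESeq2 called 7, 5 higher and 2 lower, and limma-voom with sample weights 4056, 2472 higher and 1584 lower. The unadjusted number, 801.3 by chance, was 581, 866, 1905 and 669 with 4, 1, 2 and 3 surrogate variables. It was 2229 in limma-voom and 6186 with sample weights. Without Hartley 5 months male replicate 1, 1411 genes passed, 1215 higher and 196 lower, and 4471 had an unadjusted p under 0.05, a number that was 3112 without Pigmented 5 months female replicate 1, 1085 without Hartley 5 months male replicate 2 and 1118 without Hartley 15 months male replicate 2. Across the 16026 genes, which are not independent replicates, the log2 fold changes for age in the strains had a Pearson correlation of 0.199 and a Spearman correlation of -0.0584, and over the 28 fits that left out 1 library this Pearson correlation ranged from -0.0539, without Pigmented 15 months male replicate 2, to 0.391. Among the 10219 genes with a mean of at least 10 CPM it was -0.108.

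Females and males differed in 8 genes, 6 higher and 2 lower in females (edgeR), while DESeq2 called 23, 10 higher and 13 lower, and limma-voom with sample weights 1212, 778 higher and 434 lower. ENSCPOG00000037137.1 and ENSCPOG00000037170.1 were read almost only in females: the 14 females had 17.8 ± 5.28 and 12.2 ± 3.88 CPM (SD), from 123 to 756 and from 70 to 663 counts, while the 14 males together had 1 count of each. The pooled level in females was 5516 times that in males for ENSCPOG00000037137.1 (95% exact interval 990 to 217905, counting error only) and 3875 times for ENSCPOG00000037170.1 (695 to 153101), with adjusted p = 5.7e-14 and 7.0e-13 in edgeR. ENSCPOG00000000660.4, named after its values were seen, was higher in females at 62.7 ± 6.04 against 38.7 ± 2.87 CPM (SD, n = 14 each, log2 fold change 0.68, SE 0.0535, adjusted p = 1.2e-08). ENSCPOG00000037321.1 was lower in females at 1.47 ± 0.495 against 2.36 ± 0.702 CPM (log2 fold change -0.82, SE 0.152, adjusted p = 0.0336), a call that was lost in 23 of 40 alternatives, where the adjusted p ranged from 0.000728 to 0.374. The count of 8 rose to 188 without Hartley 5 months male replicate 1. It fell to 5 without any 1 of Hartley 15 months female replicates 1 and 3, Pigmented 5 months female replicates 1, 3 and 4, Pigmented 5 months male replicates 1 and 3, Pigmented 15 months female replicates 2 and 3, and Pigmented 15 months male replicate 4.

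**Figure D5:**
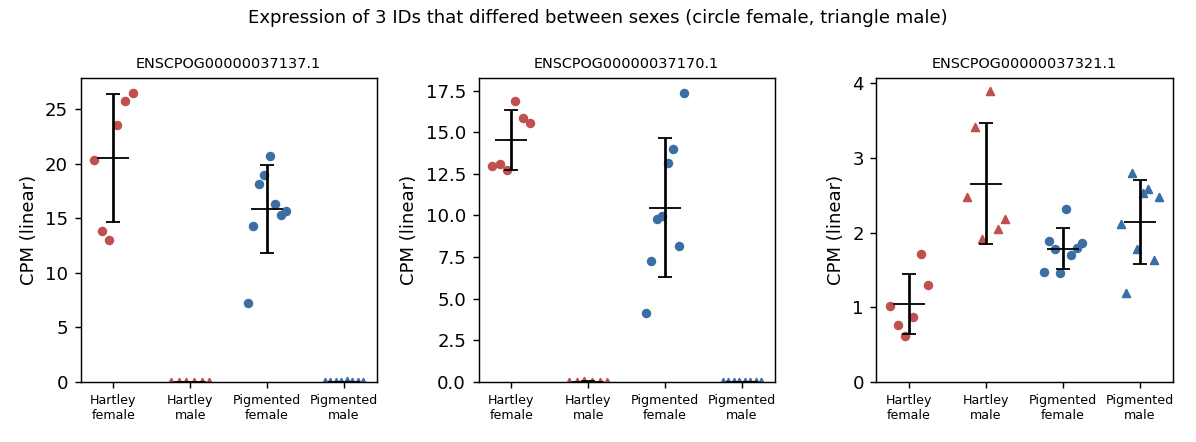
Points are CPM values (linear axis) of single animals for 3 IDs, by strain and sex, with the mean and SD as bars. The IDs ENSCPOG00000037137.1 and ENSCPOG00000037170.1 lie at 7.25 and 4.13 CPM or above in each of the 14 females and at or near 0 in the 14 males.

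The age difference did not differ detectably between females and males. The interaction of age and sex had 0 genes past the threshold in edgeR and 277 with an unadjusted p under 0.05. For comparison, 5% of the tested genes is 801.3, and the median over splits with shuffled age labels was 479. The number was 1024 without Hartley 5 months male replicate 1, and DESeq2 called 2 genes.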

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

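Chance alone marks about 1 in 20 groups when the sample farthest from the rest is compared with the range of its group. Of 104 combinations of a measure and a Pigmented group of 4 animals, 10 were marked, and 5.2 would be expected. Hartley groups have 3 animals and were not examined in this way.

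Pigmented 5 months male replicate 3 lay at 29.6 on principal component 1, while the other males of its group lay between -13.9 and -6.85, and its distance from the group mean was 0.444 in log2 CPM against 0.305 to 0.325. In that library ENSCPOG00000031413.1 was at 0.800 CPM against 1.55 to 1.72. ENSCPOG00000038111.1 was at 57.2 CPM in Pigmented 5 months female replicate 1 against 32.8 to 34.3 in the others. ENSCPOG00000007596.4 was at 4.43 CPM in Pigmented 5 months male replicate 2 against 5.00 to 5.06. In Pigmented 15 months female replicate 1, ENSCPOG00000008531.4 was at 9.38 CPM against 6.89 to 7.23 and ENSCPOG00000004337.4 at 1.84 CPM against 0.739 to 0.849. ENSCPOG00000031846.1 was at 10.2 CPM in Pigmented 15 months female replicate 3 against 14.3 to 14.6. In Pigmented 15 months male replicate 1, ENSCPOG00000037137.1 was at 0.0444 CPM, from a single read, against 0 in the others, and ENSCPOG00000037321.1 was at 1.64 CPM in Pigmented 15 months male replicate 3 against 2.47 to 2.59.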

How the results depend on the processing

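The 8 calls of named IDs for strain and the 2 of IDs read almost only in females kept their direction and their side of the threshold in each alternative run. These IDs were picked for the smallest p in the same libraries that the alternatives fit again, so such stability was likely from the start. It says nothing on the other called genes. Surrogate variables, and every setting for the comparisons averaged over strains or ages, were added after the data were seen. Over all named IDs and alternatives, 875 values were on the same side, 38 moved past the threshold, 23 fell short of it and 0 changed sign. For the counts, RLE factors, no filter, a filter at 1 CPM and limma-voom without weights stayed within 1.5 times. Sample weights raised the calls for age to 2350 in Hartley, 700 in Pigmented, 4056 for their difference and 37 over both strains, for strain to 5296 at 5 months, 639 at 15 months and 2319 over both ages, and for sex to 1212. Under shuffled age labels they called up to 4728 genes in Hartley and 2526 in Pigmented. The weighted counts for strain, sex and the difference of age effects were not set against shuffled labels, so no conclusion is drawn from them. DESeq2 gave 35, 21, 7 and 60 for the age comparisons, 325, 166 and 560 for strain, 23 for sex and 2 for age by sex. The sheet number gave 1 for age in Hartley, 39 for strain at 5 months and 154 over both ages. The 4 surrogate variables that the data called for gave 7 for age over both strains and 462 for strain over both ages, and at 5 months 84 genes, 30 higher and 54 lower (35.7% higher against 61.4%). With 1, 2 or 3 of them strain gave 53, 96 or 85 genes at 5 months, 48, 88 or 209 at 15 months and 262, 319 or 811 over both ages, age over both strains 0, 2 or 9, age in Hartley 0, 1 or 1, and sex 5, 6 or 11. With 3 the share higher was 36.5% at 5 months (31 higher, 54 lower) and 46.5% over both ages (377 higher, 434 lower, against 59.9%). Only the libraries compared gave 5 for age in Pigmented and 161 for strain at 15 months. Sex as an additive covariate gave 1 for age over both strains. The cause of these moves was not tested. Leaving out 1 library gave 0 to 2408 for age in Hartley, 0 to 0 in Pigmented, 0 to 1411 for their difference, 0 to 6 over both strains, 45 to 1937 for strain at 5 months, 38 to 106 at 15 months, 181 to 558 over both ages, 5 to 188 for sex and 0 to 0 for age by sex. The counts of 2408, 1411, 1937 and 188 all came without Hartley 5 months male replicate 1, from a fit that keeps the deviating replicate 2 of that group. For age over both strains 6 passed without Hartley 5 months female replicate 2, 4 without Hartley 5 months male replicate 3 or Pigmented 15 months female replicate 2, and 1 without Pigmented 15 months female replicate 4. For age in Hartley 1 passed without Hartley 5 months female replicate 2, Hartley 15 months female replicate 1 or 3, or Pigmented 15 months female replicate 2, the last also for the difference of strains. The correlation of age effects over all tested genes was -0.0539 to 0.391 without 1 library, and among genes at 10 CPM and above, with all libraries, it was -0.108. Tests of the gene lists were not run, since no ID has a symbol. No paired analysis was possible because each animal gave 1 library.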

Other observations

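Chosen after their results were seen were the tests of 1 deviating library, of mapping direction, of sheet order as the whole cause and of genes shared between ages, the interval set on the share kept with the sheet number, the tests of scatter with distances computed again, the relations of component 1 to library measures, and the comparisons averaged over ages or strains.

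Whether libraries of the Hartley strain are more scattered than those of the Pigmented strain stays open. Their mean distance from the group mean was 0.469 ± 0.102 in log2 CPM (SD, n = 12) against 0.383 ± 0.0617 (SD, n = 16), and shuffling these distances between the strains gave p = 0.00714 (two-sided permutation test), or 0.0239 without Hartley 5 months male replicate 2, with its group mean computed again. Distances within a group share its mean, however, and shuffling strain labels within age and sex with all distances computed again gave a permutation p of 0.0523. The difference was 0.170 at 5 months and 0.00263 at 15 months, and this change with age was not tested. Distances at 15 and 5 months had means of 0.410 and 0.430 (permutation p = 0.592, n = 14 each). No gene had at most 3 counts in every animal of 1 strain and at least 10 in every animal of the other (0 genes, 0 in shuffled labels), so by that measure no gene was read in 1 strain only, while 2 genes were so divided between females and males.

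Position on component 1 went with how broadly reads were spread over genes. Over the 28 libraries it fell with the TMM factor (Pearson r = -0.686, permutation p = 0.00012, adjusted 0.00048; Spearman rho = -0.628, p = 0.00049, adjusted 0.00196) and with the number of IDs detected (r = -0.429, permutation p = 0.0284, adjusted 0.0379; rho = -0.596, p = 0.00105, adjusted 0.0021). Without the 2 libraries farthest from the median these were -0.530 and -0.454, and within the 8 groups -0.772 and -0.532. The share of the 10 most abundant IDs gave r = 0.627 (permutation p = 0.0012, adjusted 0.0024) and rho = 0.349 (p = 0.0698, adjusted 0.0931), with r = 0.391 without those 2 libraries. Total counts gave r = -0.0780 (permutation p = 0.669, adjusted 0.669) and rho = -0.0235 (p = 0.907, adjusted 0.907). Component 1 was computed from the same counts as these measures, scaled by the same TMM factors. The relations may thus be built in to some degree and are a description. The labels give no batch for these 4 relations.

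In edgeR with all libraries strain had more genes past the threshold than age or sex, though age in Hartley had the most with an unadjusted p under 0.05. Among 100 splits of the libraries within age and sex, the real one included, 1 gave as many calls at 15 months (62 genes, highest other 15). Over both ages 2 gave as many (257, highest other 880). Again 1 gave as many genes in the same direction among the 70 and 62 with the smallest p at 5 and 15 months (30, highest other 4). At 5 months 5 gave as many calls (70, highest other 5571), so chance stays open there. The patterns were not adjusted for their number, and 100 splits allow no share under 1 in 100. Chance is thus made less likely for part of the strain difference but is not excluded. The split with 5571 calls, looked at for its count, put together Hartley 5 months male replicate 2 and the Pigmented 5-month libraries at 37.9 and 29.6 on component 1. With them were Hartley 5 months male replicate 3 (21.9) and female replicates 1 (-4.99) and 3 (13.2). Over the 100 splits the number with an unadjusted p under 0.05 at 5 months rose with the absolute difference of the 2 sides on component 1 (Spearman 0.680, a description). Component 1 is the direction of largest variance in the same counts, so such a relation was likely from the start. It gives no separate support for a structure of the samples other than strain. The sample-sheet number differs between the strains, since the first 8 libraries are all Pigmented. With it as a linear covariate 52.1% of the 257 genes stayed called (95% Wilson interval 46.05% to 58.2%), which leaves part of the calls open. That interval takes genes as independent, which they are not, and holds no spread between animals. The log2 differences of the 257 genes kept a median of 96.6% of their size (quartiles 89.1% to 105%), against a linear trend along the sheet as the whole cause. A linear term cannot take up in full a step between the first 8 libraries and the rest, so a batch of that kind stays open. Without the 2 deepest libraries 67.3% stayed called, against their depth as the whole cause, while poorer mapping of 1 strain stays open, since 59.9% of the called genes lay in the more frequent direction but the scaling centres the differences, and variants in single genes and the ancestry of the animals remain untested.

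Genes called for strain over both ages often adjoin each other in the row order of the tested genes, between which removed IDs can lie. The order of the table is not described in the sources used here. There were 19 adjoining pairs among the 257 genes, where random placement gave a mean of 4.10 and at most 15 (permutation p = 1e-05, the smallest that 100000 placements can give), and 14 of the 19 pairs went the same way. Tested genes in neighbouring rows of the full table, with no removed ID between them, also went together within groups. Their mean residual correlation was 0.164 over 10505 pairs against 0.00310 for random pairs. Among the as many top genes of 100 splits 3 gave 19 adjoining pairs or more, with a median of 8. This suggests that part of the calls are not independent of each other, and whether shared reads or shared inheritance lies behind it was not tested.

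Age may have left a weak trace, but these data do not separate it from chance. For Hartley 12 of 100 splits within strain and sex gave as many genes with an unadjusted p under 0.05 (2323, highest other 3496), for Pigmented 7 (1269, highest other 2382), over both strains 10 (1917, highest other 3296), for their difference 10 (1698, highest other 4420) and for age by sex 81 (277, highest other 4028). The medians over the other splits were 818, 403, 574, 578 and 479 in that order. With sample weights, which gave 2350 and 700 calls, 7 splits did as well in Hartley (highest other 4728) and 5 in Pigmented (highest other 2526), so those calls are within what other splits give. Without Hartley 5 months male replicate 2 the unadjusted number in Hartley fell to 1003, against 801.3 expected by chance, as it would if that library made the excess. Without replicate 1 of the same group it rose to 5528, with 2408 genes called. That fit keeps replicate 2, so the rise does not speak against a deviating replicate 2. The number also fell to 1300 without Hartley 15 months male replicate 2, so whether 1 library made the excess stays open. A difference in age itself remains open.

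The correlation of age effects between strains (0.199) was reached in 34 of 100 splits, with 0.498 as the highest other, and that of strain effects between ages (Pearson 0.313, Spearman -0.0359 across 16026 genes) in 11, with 0.461 as the highest other. The 8 genes called for sex were reached by the real split only, 1 of 100, with 2 as the highest other.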
